A study of Homo sapiens with 8 samples.

How the data were processed

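H3K27ac, a histone acetylation mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in A549, an established human lung adenocarcinoma cell line in which the oxidative stress regulator NRF2 is constitutively active. Cells received a control siRNA or an siRNA against CEBPB, a basic leucine zipper transcription factor. Per the labels' protocols, cells were harvested 48 h after transfection and the libraries were sequenced as single-end reads of 101 bases. The knockdown was done with 2 different siRNAs, called siRNA-1 and siRNA-2 here. There were 4 immunoprecipitated libraries: 2 with the control siRNA, 1 with siRNA-1 and 1 with siRNA-2. The series also has 4 input libraries, which were not analysed here on their own. The 2 siRNAs were taken as the replicates of the knockdown. The labels do not say that the 2 control libraries came from separate cultures, so the spread between them may be technical. The 2 knockdown libraries received different siRNAs, so the spread between those also includes any difference between the siRNAs.

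Per the submitters' processing notes, the tools were BWA 0.7.17, SAMtools 1.7.0 and MACS2 2.2.7.1, and the genome build was hg19. Their options, and whether the input libraries served as background, are not given in the sources used here. Sequence names in the peak lists also show a decoy sequence and unplaced contigs of that build. Each library had its own peak list, so peaks were not called on pooled samples. For each peak the deposited lists give a start, an end, a summit, a fold enrichment at the summit (a linear ratio), a −log10 p and a −log10 q. The deposited score was 10 times the −log10 q, truncated to a whole number, in over 99.9% of peaks. The highest q in the 4 lists was 0.0498. These fold enrichments and −log10 q values are the authors' own values per peak. They depend on the depth of each library, so fold enrichments were not compared between lists, and −log10 q values served to describe, rank and filter peaks. Where a region had to pass a −log10 q in 2 lists, or was ranked by the lower of its 2 values, the deeper list of a pair meets the same threshold more easily, and this was not corrected. The lists carry no read counts. The depth of each library is therefore unknown, and a region absent from a list is a region without a peak call, not a region without acetylation.

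Peaks on chromosomes 1 to 22 and X were merged across the 4 lists wherever they overlapped by 1 bp or more. A region counted as called in a library if that library had at least 1 peak in it. Lost regions were called in both controls and in neither knockdown library, gained regions in both knockdown libraries and in neither control, and kept regions in all 4. The strength of a region in a pair of libraries was the lower of its best −log10 q values in them. The 4 libraries can be split into 2 pairs in 3 ways, and the same counts were made for the other splits, which mix the treatments. No test was made per region, because 2 libraries against 2 cannot give an exact permutation p below 0.333. Shares of regions carry Wilson 95% intervals, which cover counting error over regions only, and regions are not replicates of the treatment.

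Agreement of the siRNAs was tested with Fisher's exact test (two-sided) over the regions called in both controls, with a Mantel-Haenszel odds ratio over 10 equal classes of strength. For gained regions the test ran over the regions called in both knockdown libraries, since every merged region is called somewhere and the planned table for regions absent from both controls had an empty cell by construction. Unchanged libraries were simulated 1000 times by giving each region the chance of being missed that regions of its strength had between the replicates of the reference pair. Gathering along the genome was the number of 1 Mb bins with 5 or more lost regions, against 1000 draws of as many regions from those called in both controls, matched on the 10 classes of strength (seed 1). Gained regions were drawn likewise from those called in both knockdown libraries. Chromosomes were compared by Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment over 23 chromosomes. Library totals were compared by an exact permutation test (two-sided).

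The merging and counting were run on simulated peak lists of 60669 regions. In these, 200 regions were removed from both knockdown lists and 200 from both control lists. Of these, 197 lost and 195 gained regions were recovered. Both sets were drawn from regions with a mean −log10 q of 10 or more. The recovery therefore does not cover weaker regions, where most lost and gained regions lay. Each simulated peak filled most of a single merged region, so regions could neither join nor break up. The recovery thus checks the counting and does not test how fragmented peaks are merged. All simulated lists missed regions at the rate found between the controls, which agreed more closely than the knockdown libraries. In the same simulation unchanged regions missed by chance raised the number of lost calls to 1741, but only 20 of the 217 lost calls with a −log10 q of 10 or more were unchanged regions.

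The regions and bins named in the report were fixed by a rule before the data were examined: the 10 lost and the 10 gained regions with the highest strength, the 5 bins of 1 Mb with the most lost and the 5 with the most gained regions, and the loci of CEBPB and of NOTCH3. The gene table used here is on GRCh38.p14 and the peaks are on hg19, so no coordinates of genes were used. Regions are named by position and by chromosome band, from the hg19 band table in circlize 0.4.16, and CEBPB and NOTCH3 are covered only through the bands in which these genes are known to lie. The planned promoter, gene list and sequence motif analyses need an hg19 annotation or genome and were not run. Coordinates are hg19 and count from 1.

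The alternatives fixed before the data were examined were stricter peak thresholds (−log10 q of 5 or 10), a strict threshold only where a region is called, equal numbers of peaks or equal called length per library, reciprocal overlap of 50%, merging of peaks within 500 bp, stitching of peaks within 12.5 kb, windows of 250 bp either side of summits, all sequences in the lists, leaving out each library, bins of 500 kb and fold enrichment in place of −log10 q. Requiring no peak within 1 kb of a region, the called length of stitched clusters, the counts of bins with 3 or more or 5 or more stitched clusters, and the count of bins with 3 or more regions were added after the data were seen. The stitched clusters named in the closing section fall outside the rule above and were chosen after their values were seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.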

Results

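H3K27ac peak lists from 4 libraries of A549 cells were compared to ask which acetylated regions depend on CEBPB in a lung cancer line with active NRF2. On chromosomes 1 to 22 and X, control 1 had 45537 peaks and control 2 had 45651. The siRNA-1 library had 47370 peaks and the siRNA-2 library 48216. Median peak width ranged from 670 bp with siRNA-2 to 798 bp in control 1. Merging gave 60669 regions, of which 24133 were called in all 4 libraries and 20360 in only 1. Sequencing depth is unknown for these lists, which limits what the absence of a peak can show.

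CEBPB knockdown was accompanied by missing peak calls in 4250 regions called in both controls, where simulated unchanged libraries gave a mean of 1922. The 4250 regions were 13.3% of the 32069 regions called in both controls (Wilson 95% interval 12.9 to 13.6%). The strongest was a 5403 bp region in 8q24.21 (chromosome 8, 128046455 to 128051857), with fold enrichments of 33.5 in control 1 and 31.0 in control 2. No peak was called there with either siRNA, and the nearest region called in all 4 libraries was 165 kb away. Next came a region in 1q41 (chromosome 1, 222693911 to 222697151), enriched 33.8-fold and 32.8-fold in the controls. A region in 12p13.2 (chromosome 12, 12600913 to 12604728) was enriched 21.8-fold and 25.1-fold. A region in 1p21.2 (chromosome 1, 101467483 to 101471885) was enriched 31.5-fold and 28.8-fold. The other 6 of the 10 strongest lay in 11q13.4 (chromosome 11, from 72517292), 6p23 (chromosome 6, from 13406772), 20p13 (chromosome 20, from 3292567), 7q11.23 (chromosome 7, from 77107734), 19p13.2 (chromosome 19, from 10145973) and 8q21.3 (chromosome 8, from 91478656). In both controls, all 10 of these regions ranked at or above percentile 84.7 of peaks by −log10 q. The count of lost regions rests on each library: it was 8794 without control 1 and 9716 without control 2. A region then needs a call in only 1 control, which accounts for only part of the rise. Among the regions merged from all 4 lists, 2851 were called in control 2 only and 4718 in control 1 only.

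Knockdown was also accompanied by 4103 regions called in both knockdown libraries and in neither control, where simulated unchanged libraries gave a mean of 2986. The 4103 regions were 13.6% of the 30128 regions called in both knockdown libraries (Wilson 95% interval 13.2 to 14.0%). The strongest was a 6009 bp region in 3p25.2 (chromosome 3, 13256107 to 13262115), enriched 51.2-fold with siRNA-1 and 27.7-fold with siRNA-2. A region in 13q14.12 (chromosome 13, 45779293 to 45782521) was enriched 38.9-fold and 22.1-fold. A region in 11p13 (chromosome 11, 35649599 to 35655256) was enriched 42.9-fold and 19-fold. A region in 1q41 (chromosome 1, 214738296 to 214744941) was enriched 22.3-fold and 21.4-fold. A further gained region in 3p25.2 (chromosome 3, from 12803720) lay 449 kb from the strongest. The remaining 5 of the 10 strongest lay in 2q31.3 (chromosome 2, from 181519869), 4p16.3 (chromosome 4, from 1316233), 16p12.3 (chromosome 16, from 21199191), 22q12.1 (chromosome 22, from 26866073) and 6q22.31 (chromosome 6, from 123016467). The count of gained regions was 10892 without siRNA-1 and 12718 without siRNA-2.

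Splits of the libraries that mix the treatments gave far fewer such regions. At most 797 regions were specific to a mixed pair, those called in control 1 and siRNA-1 only. Among regions with a −log10 q of 10 or more in both libraries of the pair, 704 were lost and 865 gained, against at most 8 for a mixed pair. At a −log10 q of 20 or more, 194 were lost and 248 gained, and no region was specific to a mixed pair. With called length made equal between libraries the contrast narrowed, to 3022 lost and 2477 gained regions against up to 1930 for a mixed pair, control 2 and siRNA-2. Equal length was 61.68 Mb, against 67.9 Mb in control 1 and 70.4 Mb with siRNA-1 as deposited. The setting thus cut mainly the lists of control 1 and siRNA-1, which can itself leave regions specific to control 2 and siRNA-2. With 3 splits in all, the exact permutation p cannot go below 0.333.

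**Figure D1:**
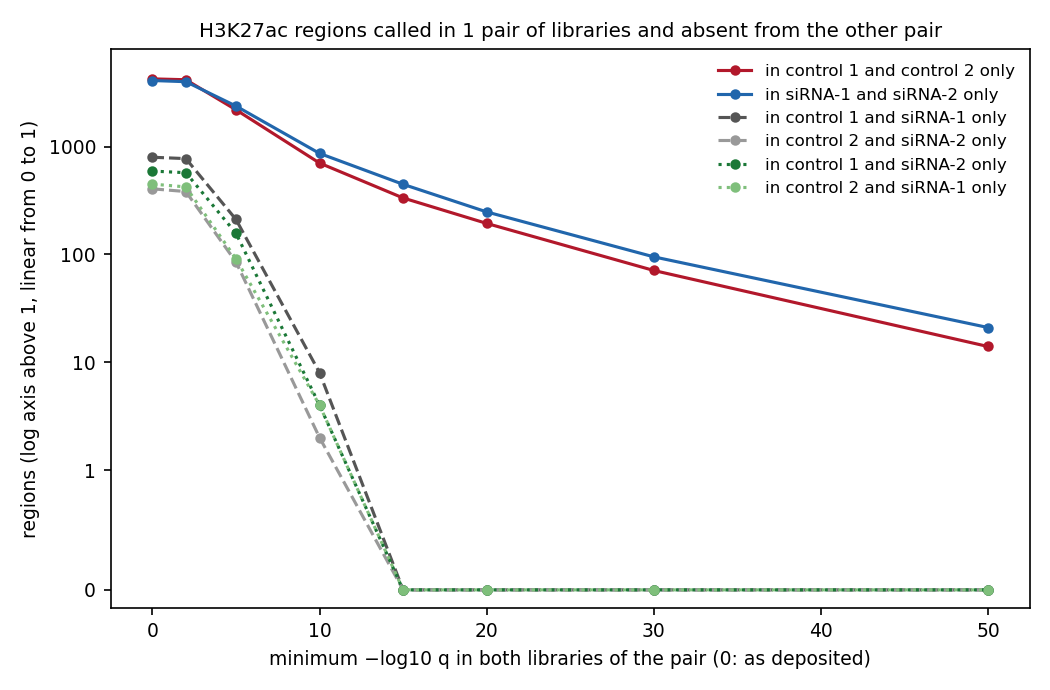
Number of merged H3K27ac regions called in both libraries of a pair and in neither other library (vertical axis, logarithmic above 1) against the lowest −log10 q required in both libraries of the pair (horizontal axis), with 1 line for each of the 6 pairs. At a minimum of 10 the control pair has 704 regions and the knockdown pair 865, while the mixed pairs have at most 8.

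Lost and gained regions were mostly among the weaker regions, and less of each was called. In control 1 the median called length was 584 bp in lost and 1589 bp in kept regions, and with siRNA-1 it was 629 bp in gained and 1646 bp in kept regions. Part of this gap comes from the definition, since a longer region more readily overlaps a peak of every list. Lost regions had a median fold enrichment of 4.91 in control 1, at percentile 33.8 of that list by −log10 q, and kept regions a median of 11.7, at percentile 71.7. Gained regions had a median fold enrichment of 5.49 with siRNA-1, at percentile 40.2, and kept regions there a median of 12.3. The regions called in both controls were divided by strength into 10 classes of about equal size. In the weakest class 42.7% were lost, and in the strongest 2 of 3207 were. In the strongest class of regions called in both knockdown libraries 0 of 3013 were gained. Disagreement between the controls alone, applied to libraries taken as unchanged, would remove 35.1% of the weakest class from both knockdown lists and 0.0368% of class 5, where 7.88% were lost. Disagreement between the knockdown libraries would give 43.9% gained in the weakest class, above the 40.9% observed, and 1.92% in class 5, where 10.5% were gained. The knockdown libraries agreed less with each other than the controls did, so the shares expected lost may be too low. Disagreement between the knockdown libraries includes any difference between the siRNAs, so the shares expected gained may be too high.

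**Figure D2:**
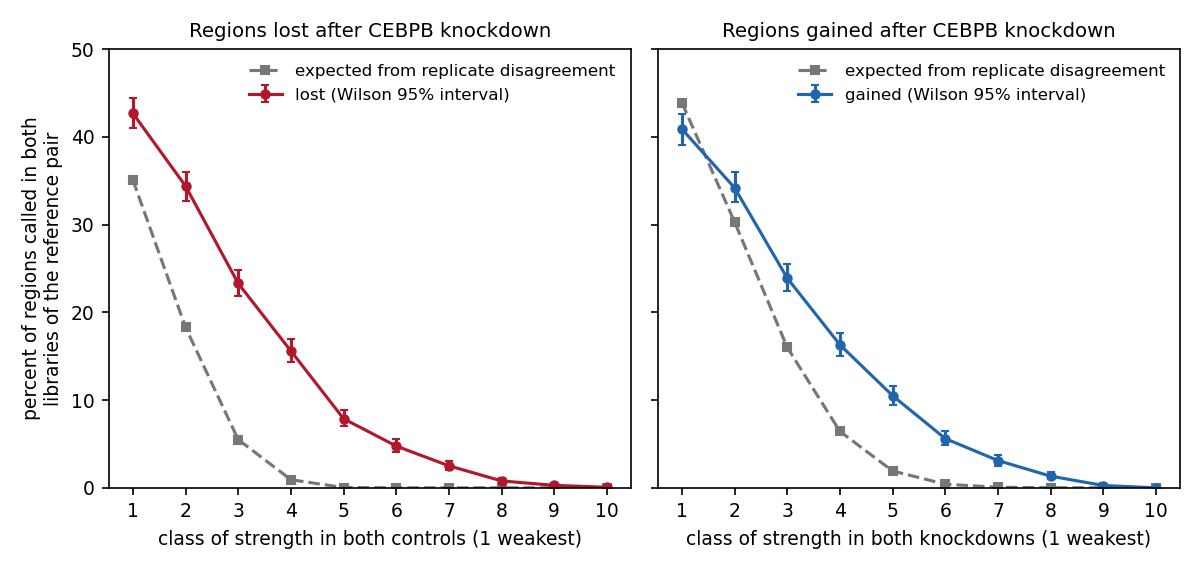
Percent of regions lost (left, of regions called in both controls) and gained (right, of regions called in both knockdown libraries) in each of 10 classes of strength (1 is the weakest), with Wilson 95% intervals over regions. Squares give the percent expected if the other pair were unchanged and missed regions as replicates of the reference pair miss each other's; in class 5 7.88% were lost against 0.0368% expected.

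Most regions missing with either siRNA were missing with both. Of the 32069 regions called in both controls, 6158 had no peak with siRNA-1 and 6028 none with siRNA-2. Of those missing with siRNA-1, 69.0% were also missing with siRNA-2. The 4250 regions missing with both compare with 1158 for independent lists, with 2320 for independent lists within classes of strength, and with a mean of 1922 (highest 2053) over 1000 simulations of unchanged libraries. The odds ratio was 30.2 by Fisher's exact test, and 12.1 by the Mantel-Haenszel method over the 10 classes. It was 47.8 among regions with a −log10 q of 10 or more in both controls and 12 for windows around summits. Over all merged regions, with each siRNA set against a different control, it was 5.12 or 4.96. Both siRNAs were compared with the same controls, so the excess over these expectations is not by itself a shared effect. The corresponding comparison for gained regions concerns agreement of the 2 controls and not of the siRNAs. Of the regions called in both knockdown libraries, 4862 had no peak in control 1 and 5236 none in control 2. The 4103 missing from both controls compare with 1684 for independent lists within classes of strength and with a mean of 2986 (highest 3105) in simulations. Every library also had regions of its own: 7951 were called with siRNA-1 only and 4840 with siRNA-2 only, against 4718 in control 1 only and 2851 in control 2 only.

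Many lost regions shared a bin of 1 Mb in some places. The bin with the most was in 5q11.2 (chromosome 5, 58000001 to 59000000), with 29 lost, 2 gained and 29 kept regions. Its lost regions had fold enrichments of at most 9.12 in either control. The highest peak of each library in the bin lay in a region called in all 4 libraries. Called length in the bin was 357 kb in control 1 and 323 kb in control 2, against 218 kb with siRNA-1 and 234 kb with siRNA-2. In peaks the siRNA-2 library lay closer to the controls: it had 102, against 122 and 124 in the controls and 75 with siRNA-1. Bins in 12p13.2 (chromosome 12, 12000001 to 13000000), 15q23 (chromosome 15, 71000001 to 72000000) and 5q15 (chromosome 5, 95000001 to 96000000) each had 16 lost regions, and a bin in 6q23.3 (chromosome 6, 136000001 to 137000000) had 15. Gained regions led in 2p23.2 (chromosome 2, 28000001 to 29000000) and 5q35.1 (chromosome 5, 169000001 to 170000000), with 14 gained and 0 lost in each. In the 5q35.1 bin the controls had 15 and 20 peaks over 22.8 kb and 21.1 kb, against 44 peaks over 73.2 kb with siRNA-1 and 49 peaks over 53.9 kb with siRNA-2. Bins in 10q22.3 (chromosome 10, 79000001 to 80000000) and 5q32 (chromosome 5, 148000001 to 149000000) each had 12 gained regions, and a bin in 1p36.13 (chromosome 1, 17000001 to 18000000) had 11. In all, 228 bins of 1 Mb had 5 or more lost regions, against a mean of 178 and at most 209 in 1000 draws matched on strength. For gained regions 204 bins did, against a mean of 155 and at most 186. The permutation p was 0.001 for each, the smallest that 1000 draws can give. Both kinds shared 13 such bins, where independence would give 17.2. The excess holds for bins with 5 or more regions and not for bins with 3 or more, which numbered 603 for lost regions against a mean of 635 in the draws, and 605 against 609 for gained regions. With peaks stitched within 12.5 kb, bins with 3 or more lost clusters numbered 83 against a mean of 66.8 (permutation p = 0.011), and bins with 5 or more numbered 3 against 1.63 (permutation p = 0.22). For gained clusters these were 94 against 83 (permutation p = 0.0689) and 6 against 2.49 (permutation p = 0.045).

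**Figure D3:**
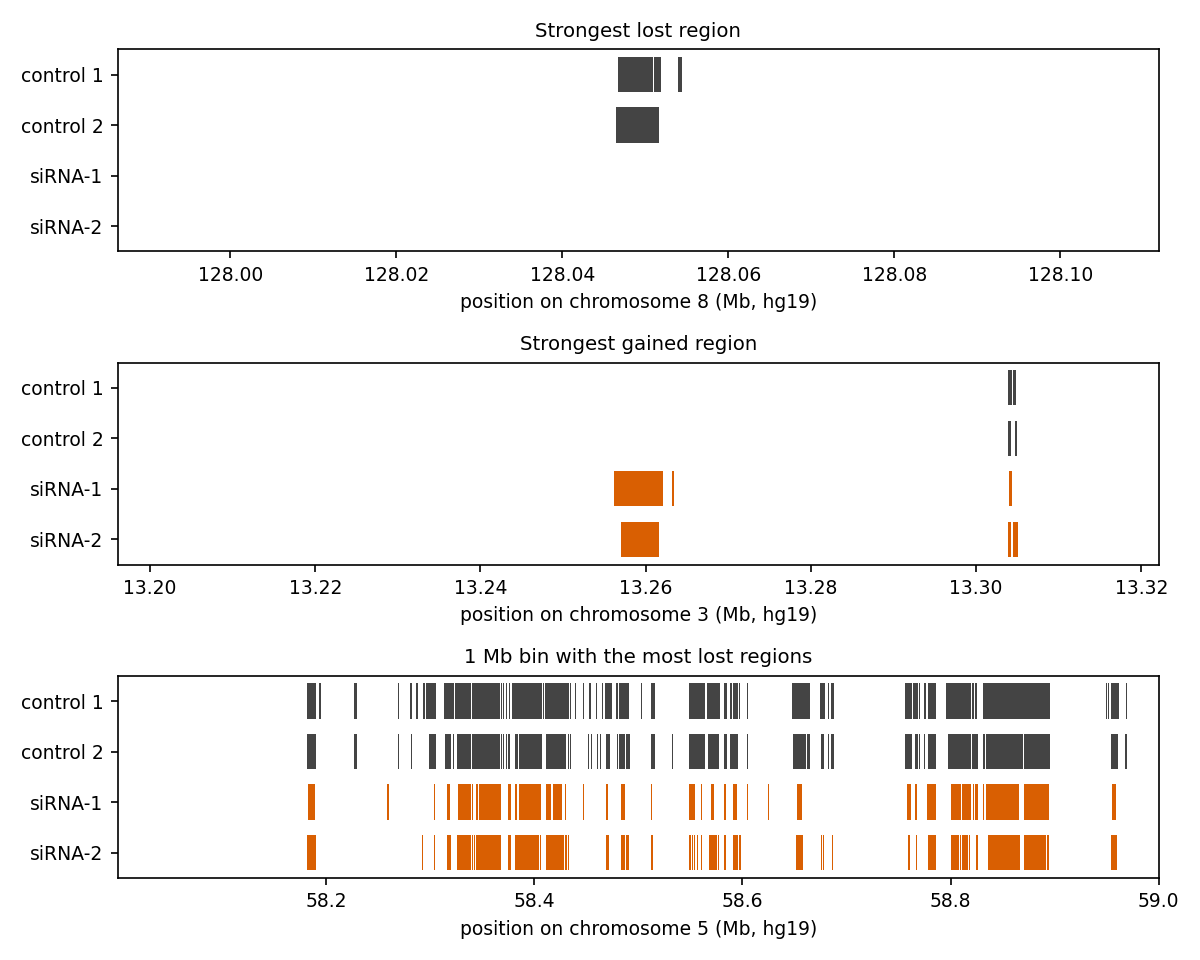
Called H3K27ac peaks (boxes, drawn to scale) in each of the 4 libraries around the strongest lost region on chromosome 8, the strongest gained region on chromosome 3, and the bin on chromosome 5 with the most lost regions; horizontal axes give hg19 position in Mb. In the chromosome 5 bin the controls have 122 and 124 peaks over 357 kb and 323 kb, and siRNA-1 and siRNA-2 have 75 and 102 peaks over 218 kb and 234 kb.

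The target of the siRNAs, CEBPB, lies in 20q13.13 (chromosome 20, 46400001 to 49800000), and the gene itself was not placed on the peaks. That band had 123 regions in control 1 and 109 in control 2, against 143 with siRNA-1 and 114 with siRNA-2. Of its 98 regions called in both controls, 9 were lost (9.18%) and 74 were called in all 4 libraries, and 12 regions were gained. None of the 9 lost regions had a −log10 q of 10 or more in both controls, and 3 of the 12 gained regions had it in both knockdown libraries. NOTCH3, a receptor of the Notch pathway, lies in 19p13.12 (chromosome 19, 14000001 to 16300000). That band had 58 and 60 regions in the controls, against 46 with siRNA-1 and 51 with siRNA-2. Of its 53 regions called in both controls 8 were lost (15.1%), again none with a −log10 q of 10 or more in both controls, and 1 region was gained. How far the siRNAs lowered CEBPB itself was not measured by these libraries.

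Lost regions were unevenly spread over the chromosomes relative to kept regions. The tests per chromosome were not matched on strength, although kept regions were stronger than lost and gained ones. They therefore do not separate chromosome from strength, and they treat regions as independent. Chromosome 8 had 255 lost against 1096 kept regions (odds ratio 1.34, adjusted p = 0.000504, Fisher's exact test), and chromosome 19 had 89 against 999 (odds ratio 0.495, adjusted p = 1.81e-10). In all, 9 of 23 chromosomes passed an adjusted p of 0.05 for lost regions. For gained regions 2 did: chromosome 19 (87 gained, odds ratio 0.502, adjusted p = 8.02e-10, Fisher's exact test) and chromosome 5 (259 gained, odds ratio 1.25, adjusted p = 0.0225, Fisher's exact test). Among regions with a −log10 q of 10 or more in the pair that had them, 0 chromosomes passed for lost regions (4 at an unadjusted p under 0.05 by Fisher's exact test) and 1 for gained regions. Set directly against gained regions, lost regions were not spread differently on any chromosome after adjustment (Fisher's exact test, 0 of 23, lowest adjusted p = 0.0776; 5 had an unadjusted p under 0.05).

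Both knockdown libraries had more peaks than both controls, while called length did not separate the treatments. Knockdown libraries had 47793 ± 598 peaks (mean ± SD, n = 2) and controls 45594 ± 80.6 (n = 2), a difference of 4.82% that was larger than the spread between replicates (exact permutation p = 0.333, the smallest that 2 against 2 can give). Called length was 66.1 ± 6.19 Mb after knockdown (n = 2) and 65.0 ± 4.12 Mb in controls (n = 2), a difference within the spread between replicates (exact permutation p = 1). Called length followed the number in the labels instead: it was 67.9 Mb in control 1 and 70.4 Mb with siRNA-1, against 62.1 Mb in control 2 and 61.7 Mb with siRNA-2. Within number 1 the knockdown library had 2.54 Mb more than the control, and within number 2 the knockdown minus control difference was -0.39 Mb. Within the numbers, the knockdown library had 1833 and 2565 more peaks than the control. Which bases were called did follow the treatment. The Jaccard index of called bases was 0.765 between the controls and 0.659 between the knockdown libraries, against 0.574 to 0.613 between a control and a knockdown library. The mean within pairs was 0.712 for the real split and at most 0.596 for the others.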

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

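Peaks outside chromosomes 1 to 22 and X enter no comparison above, and unplaced contigs of the genome build carried slightly more of them after knockdown: 42 peaks with siRNA-1 and 41 with siRNA-2, against 36 in each control. This was picked out because both knockdown libraries lay above both controls. On the decoy sequence the knockdown libraries had 82 and 96 peaks and the controls 91 and 101. All peaks outside chromosomes 1 to 22 and X, including those on neither kind of sequence, did not separate the treatments. They numbered 154 and 171 in the controls, against 153 with siRNA-1 and 160 with siRNA-2. On chromosomes 1 to 22 and X the knockdown libraries also had more peaks, by 4.82% of the control mean.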

How the results depend on the processing

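Requiring no peak within 1 kb, bins with 3 or more lost regions and bins of stitched clusters were alternatives chosen after seeing the data. Lost regions numbered 2137 and gained regions 2423 with a −log10 q of 10 or more everywhere. They numbered 704 and 865 with that threshold only where called, and 1488 and 1629 after stitching within 12.5 kb, where fewer and larger units are counted by construction. Reciprocal overlap of 50% gave 7641 lost regions and equal called length 2477 gained regions; the cause was not tested. Without each library in turn, lost regions ranged from 6256 to 9716 and gained regions from 4904 to 12718, partly since fewer calls or fewer absences are then required. The knockdown minus control difference in called length ranged from -3.305 to 5.455 Mb, and was -1.84 Mb without control 2 and -3.305 Mb without siRNA-1. Called length follows the label numbers, and leaving out either library unbalances them; within the numbers the differences were 2.54 and -0.39 Mb. Bins with 3 or more lost regions numbered 603, under the mean of 635 in the draws, and bins with 5 or more stitched clusters 3, no longer past the threshold (permutation p = 0.22); the cause was not tested. The number of chromosomes past the threshold went from 11 (lost and gained together) to 1 at a −log10 q of 10 or more where called, where fewer regions enter. The other 43 values kept their direction or their side of the threshold, and counts of lost and gained regions among them stayed within 1.5 times. Among these, bins with 5 or more lost regions numbered 146 at 500 kb, where the draws had a mean of 65.4, and 228 at 1 Mb, where they had 178, and the difference in peaks was 1420 at a −log10 q of 10 or more, against 2199. Setting each siRNA against a different single control leaves the same 4250 regions missing by construction, so it says nothing on the shared controls. The odds ratio for agreement of the siRNAs ranged from 4.96 to 47.8, against 30.2. With the numbers in the labels as a block, the paired difference in peaks was again 2199 (exact sign-flip p = 0.5, the smallest that 2 pairs can give) and that in called length 1.075 Mb (p = 1, exact). Region by region, libraries of the same number showed little common deviation (correlation across regions 0.000907 for presence, 0.0642 for called length of kept regions). Library-wide called length did follow the numbers. Peak names start with 000858Y in control 1 and 000859Y with siRNA-1, and with 000862Y in control 2 and 000863Y with siRNA-2. Libraries of the same number thus have adjacent prefixes, but the labels do not say whether they were made together. With only 2 pairs and no label that states a pairing, the numbers were not taken as pairs. The alternatives of the promoter, gene list and motif analyses were not run. Depth is unknown, which limits every statement on absence.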

Other observations

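In this part the called length of stitched clusters, the test of label numbers, stitched clusters at 5 or more and regions at 3 or more per bin were chosen after the result was seen. The −log10 q of 10 and equal called length were alternatives fixed before the data were examined, but the former was taken as a test of weak peaks only after its result was seen. Stitched clusters at 3 or more per bin were chosen after the data but before that result was seen. Broad acetylated clusters differed in called length as well as in presence. Peaks within 12.5 kb were stitched into 26072 clusters, and the called length inside each was compared between libraries. In 163 clusters both controls exceeded both knockdown libraries by at least 5 kb, and in 95 the reverse held. Mixed pairs of libraries gave at most 8 such clusters, and at a gap of 10 kb 32 and 14 clusters against 0. At a gap of 1 kb, where the treatments gave 2010 and 1933 clusters, control 1 and siRNA-1 together gave 300 and the other mixed pairs at most 31. The gap of a cluster was the smallest difference between a control and a knockdown library. The largest gap was in 5q11.2 (chromosome 5, 58258279 to 58516109), with 151 kb and 134 kb called in the controls, 90.0 kb with siRNA-1 and 107 kb with siRNA-2. Next by size of the gap came a cluster in 8p22 (chromosome 8, 17609588 to 17781893), with 98 kb and 90.2 kb in the controls, against 68.1 kb and 67.4 kb. A cluster in 2p21 (chromosome 2, 42033199 to 42101883) followed, with 47.1 kb and 43.1 kb in the controls, against 24.7 kb and 19.5 kb. A compact cluster in 20p13 (chromosome 20, 4931272 to 4959480) was singled out for its ratio: it had 23 kb and 22.4 kb called in the controls and 5.56 kb and 5.28 kb after knockdown, and none of its 4 regions was lost outright.

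Other clusters were longer in both knockdown libraries. The largest gap in that direction was in 4q32.3 (chromosome 4, 169400524 to 169484097), with 14.3 kb and 14.0 kb called in the controls, 37.6 kb with siRNA-1 and 34.3 kb with siRNA-2. In 9q31.3 (chromosome 9, 114719834 to 114838534) the siRNAs differed, with 76.0 kb for siRNA-1 and 40.1 kb for siRNA-2, against 21.9 kb and 19.1 kb in the controls. A cluster in 8p12 (chromosome 8, 32081161 to 32216383) came next, with 52 kb and 53 kb in the controls, against 81.2 kb and 69.7 kb. Means of controls and knockdown libraries lay further apart in 9q31.3 (20.5 and 58 kb) and 8p12 (52.5 and 75.4 kb) than in 4q32.3 (14.2 and 35.9 kb). A cluster in 14q24.1 (chromosome 14, 69141301 to 69171962), singled out for its ratio, had 3.68 kb and 1.76 kb in the controls, against 21 kb and 15.6 kb. Called length depends on depth, which is unknown, and no test was made for each cluster. In each direction the 3 with the largest gap are named, and the 20p13 and 14q24.1 clusters were added for their ratio after their values were seen.

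The number of treatment-specific regions is the pattern most open to technical explanation. Weak peaks on either side of the calling threshold would give every pairing of libraries similar numbers, but 704 lost regions had a −log10 q of 10 or more in both controls against at most 8 in mixed pairs. Among weaker regions this explanation stays open for part of the calls. Simulated unchanged libraries gave a mean of 1922 lost regions, against 4250 observed, and 2986 gained regions, against 4103. The 1922 rests on misses between the controls, which agreed more closely (Jaccard index 0.765) than the knockdown libraries (0.659), so it may be too low. The 2986 rests on misses between the knockdown libraries, which received different siRNAs, so it may be too high. Different numbers of calls per library are argued against by equal numbers of peaks. These left 3723 gained regions, the smaller of the 2 counts, against at most 807 in mixed pairs. With equal called length, however, the 2477 gained regions came closer to the 1930 of a mixed pair, control 2 and siRNA-2. That setting cut mainly the lists of control 1 and siRNA-1, which can itself leave regions specific to the other 2 libraries. Library-wide called length followed the numbers in the labels, and whether a library batch lies behind this is unknown. Each treatment has 1 library of each number, so such a batch would give regions specific to a number. There were 797 and 406 of these, against 4250 lost and 4103 gained regions. At a −log10 q of 10 or more there were 8 and 2, against 704 and 865. Regions specific to a number were thus fewer than regions specific to a treatment. These counts belong to the comparison that made the pattern, so they are no separate test and cannot decide on such a batch. With equal called length control 2 and siRNA-2 had 1930. An effect of CEBPB loss stays open as the biological explanation, as do differences between control and knockdown siRNAs other than CEBPB and a batch that follows the treatment, none of which these 4 libraries can separate. The prefixes of the peak names alternate between control and knockdown libraries, but they do not tell how the libraries were processed.

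The gathering of changed regions in bins of 1 Mb has a candidate technical explanation. Density of regions alone is argued against by the draws from the regions called in both controls, which reached at most 209 bins with 5 or more, against 228 observed. A broad domain called as several fragments could produce the gathering, and the tests leave this open. With peaks stitched within 12.5 kb, 83 bins had 3 or more lost clusters, above the mean of the draws (66.8, permutation p = 0.011) but not above their highest (88), and 3 bins had 5 or more, against a mean of 1.63 (permutation p = 0.22). Unstitched regions at 3 or more per bin showed no excess (603 against a mean of 635). The counts of stitched clusters are small, and they do not show that stitching weakened the gathering.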
